A study of Mus musculus with 3 samples.

How the data were processed

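Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in the mouse ECOMG myeloid progenitor line. Per the labels, NIPBL, the factor that loads cohesin on chromatin, carried an FKBP12 degron, cells grew with GM-CSF and estradiol, and each library was made from 50000 cells with a commercial kit. The 3 libraries were taken at 0 h without dTAG (the small molecule that leads to breakdown of the tagged protein), at 6 h with dTAG and at 72 h with dTAG. Each group held 1 library, so no difference between time points has a replicate check and no test across conditions was run.

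The authors deposited 1 peak list per library, called separately for each. The submitters' processing notes name FastQC 0.11.8, MultiQC 1.10.1, BWA 0.7.17, MACS2 2.2.7, bedtools 2.30.0, ChIPseeker, edgeR, limma and HOMER, and the genome build mm10, with no options. Which fragments entered peak calling, how duplicates were treated and whether read ends were shifted are not given in the sources used here. Each line of the deposited lists gives a position, a fold (the ratio of the summit to the peak caller's background) and the −log10 p-value and −log10 q-value of the peak, as the authors' peak caller wrote them. Each fold is the peak's own value and was used to describe, rank or filter peaks within its list. The lowest −log10 q was 1.45 at 0 h, 1.44 at 6 h and 1.64 at 72 h, just above the 1.30 that corresponds to a q of 0.05.

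Read totals were not used here. In each list 100% of the folds lay on an even grid, with a tolerance of 0.01 of a step. If the caller formed the fold as summit fragments plus 1 over background plus 1, with 1 background per library, the grid gives a background of 0.323 fragments at 0 h, 0.327 at 6 h and 0.281 at 72 h. The 6 h and 72 h backgrounds were then 1.01 and 0.870 times that of 0 h, which served as the estimate of relative depth, and the lowest summit in each list was 3 fragments. A locus without a region in a list can therefore hold signal below that minimum, or over a stretch shorter than the shortest listed region of 55 bp at 0 h, 56 bp at 6 h or 58 bp at 72 h.

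Peak lines were read as regions on chromosomes 1 to 19, X and Y, and 0 lines needed merging. Regions of 2 lists were matched when they shared at least 1 bp. A region was strong when it lay in the upper 50% of its own list by −log10 q, ties at the cutoff included. The cutoff was 7.82 at 0 h, 9.25 at 6 h and 13.0 at 72 h. Regions gained at 72 h thus met a stricter cutoff than those lost. Strong regions numbered 98492, 92810 and 76050. A strong region was called lost when no region of any strength in the later list overlapped it, and gained when it was strong in the later list with no overlap in the earlier one. Shares have exact Clopper-Pearson 95% intervals, and ratios of region counts have exact 95% intervals from the binomial split of both counts. These intervals cover counting error only. Those of ratios treat both counts as independent although many regions were listed at both times, so they do not describe a paired change.

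Gene positions came from a RefSeq annotation of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. It gave the span of each gene without strand, so the planned promoter windows were replaced by windows of 1 kb around either end of a protein-coding gene, and the nearest start site by the nearest gene end. The spans include outer predicted transcripts, so the main start of a gene can lie inside its span, as at Nipbl. A locus is the gene span with 10 kb on each side. Of 438 list entries in 18 gene lists, 435 matched a symbol and 3 (Azu2, Mx1 and Mx2) did not. For each list the regions in its loci were summed, so that a region in overlapping loci counted for each gene, divided by the same change over all coding loci, and ranked among 10000 random lists of the same size matched on mean regions in 10 bins. A percentile of at least 97.5 or at most 2.5 is called outside the range of random lists, as a description of these libraries. The random lists were not matched on gene density or on gene ends, so the position of a list's genes may contribute to its percentile. The rank of a gene end is its percentile by height within its own library, among the 12616 genes with an end region in all 3 lists. Gene density was the number of protein-coding genes per 1 Mb bin, in 3 equal parts.

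The genes named per comparison followed a rule set before the data were examined: strong lost and gained regions were assigned to the nearest gene end within 100 kb, genes were ranked by lost minus gained or the reverse, and the first 10 of each direction were taken, leaving out predicted and clone-named genes. List members are named as examples where an end region was present in one list and absent in another, or where the number of regions in the locus differed most. Others are named outside this rule, such as by end rank or by strong regions, and not every member that met it is named. Motif shares had been planned and were not run, since they need the genome sequence.

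Alternatives covered a stricter q, lists cut to equal size, stricter overlap rules, other definitions of strong, other gene-end and locus widths, and another assignment of regions to genes. Alternatives added after the data were seen were common minimum folds of 10 and 20, leaving out chromosome 15, merged regions of all 3 lists in place of each list's own, and counting each region once per gene list where loci overlap. On simulated data the overlap code found 200 of 200 strong regions removed from the 0 h list and gave the same overlaps as bedtools. In simulations from the 0 h locus counts of 21887 genes, lists raised 1.25-fold passed the 97.5th percentile in 79.5% of draws. Lists raised 1.5-fold did so in 100% and unraised lists in 1.5%. The simulated lists held random genes with independent counts. Curated lists, overlapping loci and regions shared between libraries were not simulated. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.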

Results

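Accessible chromatin was mapped in NIPBL-degron myeloid progenitors before dTAG and after 6 h and 72 h of dTAG, with 1 library at each time and hence no replicate check on any difference. The lists held 182233 regions at 0 h, 178055 at 6 h and 145044 at 72 h, covering 34.1, 34.3 and 29.9 Mb. Median region length was 130, 135 and 153 bp. The shorter list at 72 h lacked mainly weak regions: regions with a −log10 q of at least 10 numbered 82233, 85429 and 81072. Regions within 1 kb of an end of a protein-coding gene made up 15.9% (15.8 to 16.1) of the list at 0 h, 15.9% (15.7 to 16.0) at 6 h and 19.1% (18.9 to 19.3) at 72 h.

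The Nipbl locus itself (chromosome 15, 8289824 to 8465315, mm10) stayed accessible in all 3 libraries, with 27 regions at 0 h, 31 at 6 h and 30 at 72 h. Its highest region lay inside the gene span, at 8443555 to 8445663 with a fold of 113 at 0 h and at 8443527 to 8445653 with a fold of 130 at 6 h. At 72 h it lay at 8445326 to 8445645 with a fold of 133. The same stretch was then listed in pieces, with regions also at 8443517 to 8445008 (fold 103) and 8445114 to 8445220 (fold 9.37). The degron acts on the protein, so accessibility of the gene does not check its depletion. The locus of Mau2, the partner of NIPBL in the loader, held 10, 12 and 7 regions, that of Rad21, a core cohesin subunit, 6, 7 and 8, and that of Ctcf, the factor that stops loop extrusion, 11, 14 and 16.

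The first comparison set the library at 6 h with dTAG against that at 0 h without it. NIPBL protein levels were not among the data used here. No library without dTAG was analysed at 6 h or 72 h, so dTAG, time and library cannot be told apart. Few strong regions differed, and the blood-cell lists lay inside the range of random lists by regions in their loci: those of mature neutrophil genes held 235 regions at 0 h and 231 at 6 h, those of progenitor and stem genes 317 and 317, and those of secondary and tertiary granule genes 261 and 262. Of the 98492 strong regions at 0 h, 97.5% (97.4 to 97.6) were overlapped at 6 h. Hoxa9 and Hoxa7, homeobox genes of progenitors, had an end region at 0 h and none at 6 h. Their loci, which overlap and so share counted regions, went from 8 to 3 and from 10 to 4 regions. Meis1, the cofactor of both, had an end region at 6 h and not at 0 h. By nearest gene end, 0 strong regions were lost near Hoxa9 or Hoxa7 at 6 h and 0 gained near Meis1. Of all weak 0 h regions, 51.9% were overlapped at 6 h.

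Strong regions lost at 6 h numbered 2446, or 2.48% (2.39 to 2.58) of the strong 0 h regions, and those gained numbered 1587, or 1.71% (1.63 to 1.80) of the strong 6 h regions. With a common −log10 q minimum of 10 the order turned, with 688 lost and 893 gained, so neither direction prevailed. Of all 0 h regions, 76.6% (76.4 to 76.8) were overlapped at 6 h, and 78.2% (78.1 to 78.4) of 6 h regions were overlapped at 0 h. Overlap followed height: it was 38.5% (38.0 to 38.9) in the weakest 25% of the 0 h regions and nearly complete in the strongest 25%, where 20 of 45558 were missing.

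**Figure D1:**
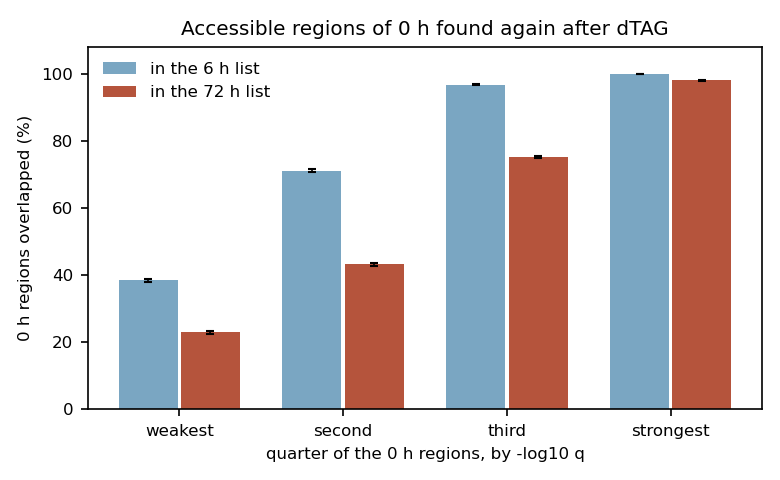
Percent of 0 h regions overlapped in the 6 h list and in the 72 h list (y axis), for the 0 h regions in 4 equal parts by −log10 q (x axis), with 1 library per time and bars on the columns for the exact 95% binomial interval. In the weakest part 38.5% were overlapped at 6 h and 22.9% at 72 h, and in the strongest part 98.0% were still overlapped at 72 h.

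Genes with the most strong regions lost at 6 h were Eef2, Csf2ra, Rere, Slc28a3, Clpb, Dnaaf3, Fli1, Ank2, Mtss1 and Tacc1, with 2 to 4 such regions each. Tacc1, with 2, entered through the order of ties, by a high and narrow region of fold 139 at chromosome 8, 25200156 to 25200257. Eef2, the translation elongation factor, led with 4, and its locus held 26 regions at 0 h and 15 at 6 h. Fli1, an ETS factor of blood cells, lost 3 strong regions, and its locus held 41 and 35 regions. Csf2ra encodes the alpha chain of the GM-CSF receptor, and its lost regions included one at chromosome 19, 61263804 to 61263867, 35370 bp outside the gene. Genes with the most strong regions gained at 6 h were H2-D1, Sertad2, Tmem131, Shisal1, Srrm1, Eva1c, Hoxc9, Cmip, Actr2 and Hlx, with 2 or 3 each. In all, 2446 strong regions were lost and 1587 gained, with 21887 coding genes. Counts of 2 to 4 per gene were not compared with random placement, so they do not single these genes out. Both lists were compared with another assignment, which counted regions inside the gene span with 10 kb on each side. By it, 3 of the 10 lost and 2 of the 10 gained genes were shared. Tied genes were then ordered by symbol instead of by their strongest region, so assignment and ties were not separated.

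Among the 18 gene lists at 6 h, 3 lay outside the range of random lists by regions in their loci. Housekeeping genes held 340 regions at 0 h and 301 at 6 h, 0.906 (0.773 to 1.06) of the change over all loci and percentile 0.43, with Eef2 at 26 and 15 and Hsp90ab1, a chaperone, at 23 and 13. Non-myeloid tissue genes held 178 and 153 regions, a ratio of 0.880 (0.704 to 1.10) at percentile 1.93, and 17 of the 30 had an end region at 0 h against 12 at 6 h, at percentile 0.195. The cohesin list, of cohesin subunits and regulators, loading factors and Ctcf, also includes condensin genes and Smc5 and Smc6, so its values are not those of cohesin genes alone. It held 255 and 273 regions, a ratio of 1.10 (0.921 to 1.31) at percentile 98.1, with Stag2 at 9 and 15. The counting intervals of all 3 ratios included 1, while their percentiles lay outside the range of random lists. The intervals treat both counts as independent although many regions were listed at both times, so they cannot decide these shifts. With 1 library per time the shifts were left undecided. By end ranks, interferon response genes lay outside the range of random lists at 6 h, with a median change of 2.30 points over 25 members at percentile 98.7.

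The second comparison set the library at 72 h with dTAG against that at 0 h without it, with the same limit. Loci of mature neutrophil genes held more regions at 72 h although the list as a whole was shorter: 302 against 235 at 0 h, 1.50 times (1.26 to 1.79) the change over all loci and above all 10000 random lists, at percentile 100. Fpr1 and Fpr2, receptors for formylated bacterial peptides, had no region at a gene end at 0 h or 6 h and had one at 72 h. Their loci, which overlap, went from 7 to 14 and from 4 to 12 regions. A region in overlapping loci counts for each gene; counted once, the list held 231 and 284 regions, 1.45 times (1.22 to 1.74) the change over all loci at percentile 100. In the opposite direction, Kit, the stem cell factor receptor, held 7 regions at 0 h, 5 at 6 h and 0 at 72 h. At 0 h the highest Kit regions had folds of 18.9 and 10.6, and the rest 3.02 to 4.54, near the lowest listed. By nearest gene end, 3 strong regions were lost near Kit at 72 h and 1 was gained. Bcl11a, a transcription factor of lymphoid and stem cells, held 7, 6 and 0 regions.

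Of the 28 mature neutrophil genes, 20 loci held more regions at 72 h than at 0 h, 5 held fewer and 3 the same number. The 5 were Selplg (24 and 20), Mxd1 (17 and 12), Csf3r (11 and 8), Ifitm1 (10 and 8) and Csf3 (8 and 7). Whether the gain is particular to neutrophil genes rather than to genes of myeloid cells in general was not tested. S100a8, a subunit of calprotectin, went from 7 to 15 regions, Clec4n, a C-type lectin receptor, from 5 to 13, Trem1, an activating receptor of myeloid cells, from 6 to 12, and Trem3 from 5 to 10. Near these 28 genes 38 strong regions were gained and 21 lost, against medians of 7 gained and 18 lost in random lists, and Ccl6, a chemokine, accounted for 8 of those gained. End regions also stood higher within their own library: the median rank change of the 22 ranked members was 13.0 percentile points, at percentile 100. Il1r2, the decoy interleukin 1 receptor, went from rank 24.5 to 94.9, S100a9 from 26 to 67 and Cd14, a lipopolysaccharide co-receptor, from 24 to 62. With only regions of fold 10 or more, the list's loci held 107 and 163 regions, 1.36 times (1.06 to 1.75) the change over all loci.

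Several other lists, of differing function, also lay above the change over all loci. Secondary and tertiary granule genes held 261 regions at 0 h and 292 at 72 h, 1.31 times (1.10 to 1.55) the change over all loci at percentile 99.97. Cybb, the catalytic subunit of the phagocyte oxidase, went from 5 to 12 regions and Mmp9, a gelatinase, from 11 to 16, and both had an end region at 72 h only. Mmp8, the neutrophil collagenase, held 8 and 15. Above a fold of 10 this list stood at 1.09 (0.855 to 1.38), percentile 80.6, inside the range of random lists. Targets of p53 and apoptosis genes held 284 and 317 regions, a ratio of 1.31 (1.11 to 1.54) at percentile 99.99, with Mcl1 at 14 and 22 and Bcl2 at 29 and 41, both survival genes; above a fold of 10 the percentile was 95.3. Interferon response genes held 192 and 202, a ratio of 1.23 (1.01 to 1.51) at percentile 99.9, with Irf1 at 8 and 14; with 50 kb flanks the ratio was 1.09 (0.968 to 1.23) at percentile 96.5. Inflammatory and NF-kB genes held 334 and 337, a ratio of 1.18 (1.01 to 1.38) at percentile 99.4, and 24 strong regions were gained near them, 5 of them near Tnfaip3, the NF-kB inhibitor A20.

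The cohesin list, with its condensin genes, Smc5 and Smc6, held 255 and 259 regions, a ratio of 1.19 (0.996 to 1.42). Its percentile was 98.4, against 76.9 when merged regions were counted and 93.2 with 50 kb flanks. Nuclear envelope and lamina genes held 398 and 403, a ratio of 1.19 (1.03 to 1.37) at percentile 96.9. Lmnb1, a B-type lamin, held 24 and 29 regions, Lmna 32 and 26, Lbr, the lamin B receptor, 10 and 8, and Syne1, a nesprin, 50 and 67.

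Progenitor and stem genes as a list held 317 and 282 regions, a ratio of 1.04 (0.884 to 1.23) at percentile 56.9. Of the 21 genes, 18 had an end region at 0 h and 14 at 72 h, at percentile 3.67 and inside the range of random lists, while over all coding genes the numbers were 14042 and 12943. The median rank change of the 14 ranked members was −5.74 points, at percentile 2.36. Near the list 25 strong regions were lost and 17 gained, against medians of 16 and 8 in random lists, at percentiles 93.3 and 98.3. Kit, Bcl11a, Hoxa9 and Hoxa7 had an end region at 0 h and none at 72 h. The end rank of Myc went from 56 to 16 and that of Myb from 26 to 11, while 3 strong regions were gained near Myc. Of the 21 loci, 6 held more regions at 72 h than at 0 h, 13 fewer and 2 the same number. Etv6 went from 41 to 58 regions and Runx1 from 51 to 58. Myeloid transcription factors held 276 and 268 regions, a ratio of 1.14 (0.957 to 1.35), with 8 loci holding more, 9 fewer and 5 the same number. The end rank of Runx3 went from 96 to 40 and its locus from 29 to 21 regions. The end rank of Gfi1 went from 48 to 18 while its locus went from 18 to 25 regions. Cebpb gained 5 strong regions. Primary granule genes held 191 and 177 regions, a ratio of 1.08 (0.879 to 1.34), with Elane, neutrophil elastase, at 24 and 13, its neighbour Prtn3, whose locus overlaps it, at 27 and 16, and Ctsc, their activating protease, at 10 and 18. Cell cycle and replication genes held 392 and 377, a ratio of 1.13 (0.975 to 1.30), with Mki67 at 6 and 13 and Cdk4 at 21 and 13.

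Lists of other lineages and control genes went different ways. Non-myeloid tissue genes went from 178 to 106, 0.697 (0.543 to 0.892) of the change over all loci at percentile 0.28 (3.15 in equal-sized lists and 3.56 above a fold of 10), with Krt5 at 4 and 0 and Cdh5 at 11 and 3. Erythroid and megakaryocyte markers held 172 and 125, a ratio of 0.851 (0.670 to 1.08) at percentile 6.67, with Zfpm1, the GATA1 cofactor, at 39 and 26. Lymphoid markers held 162 and 120, a ratio of 0.867 (0.679 to 1.10) at percentile 13.3, with Pax5, the B-cell factor, at 15 and 1. Mast cell, basophil and eosinophil markers held 79 and 57, a ratio of 0.845 (0.590 to 1.20) at percentile 37.9 (1.58 above a fold of 10), with Il5ra at 6 and 0. Dendritic cell markers held 193 and 183, a ratio of 1.11 (0.902 to 1.37), and housekeeping genes 340 and 290, a ratio of 0.999 (0.851 to 1.17). Monocyte and macrophage markers held 147 and 149, a ratio of 1.19 (0.939 to 1.50) at percentile 97.2, just inside the range of random lists; it lay outside at 99.3 in equal-sized lists, 98.9 with merged regions, 99.7 above a fold of 10 and 99.4 with each region counted once. Adgre1, the F4/80 antigen, held 13 and 42. Without Adgre1 they held 134 and 107, a ratio of 0.935 (0.718 to 1.21), and Marco, a scavenger receptor, held 4 and 0. The end ranks of the monocyte list had a median change of 5.67 points over 14 members, at percentile 98.4. Near it 12 strong regions were gained, 4 of them near Adgre1, and 20 were lost, against medians of 4 gained and 12 lost in random lists, at percentiles 98.9 and 94.9.

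**Figure D2:**
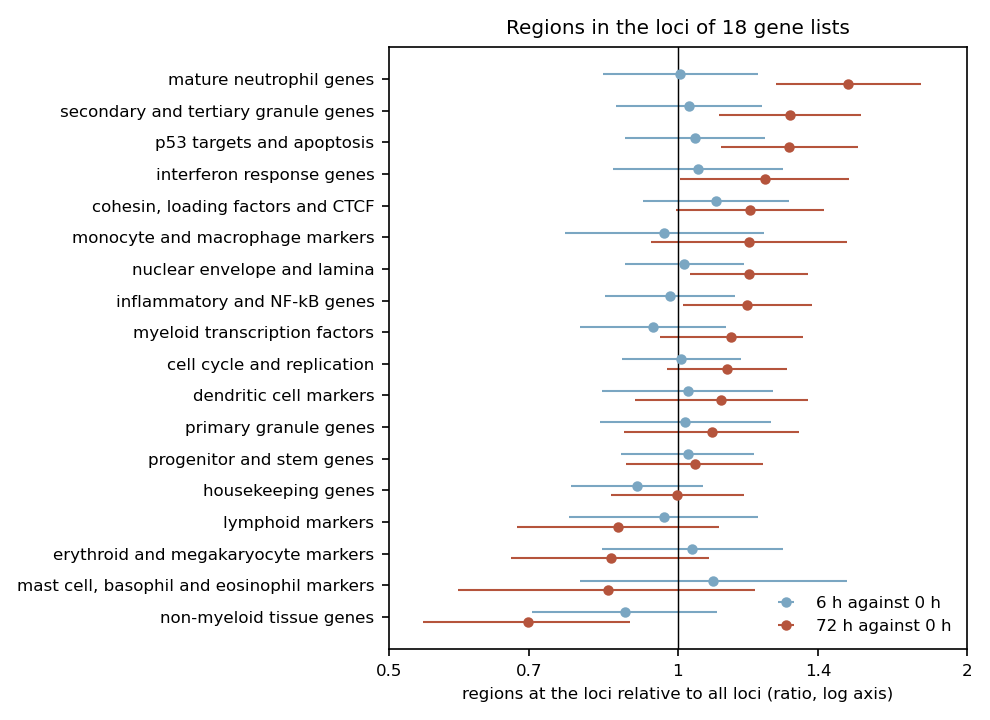
Regions in the loci of each of the 18 gene lists at 6 h and at 72 h, as a ratio to 0 h divided by the same ratio over all coding loci (x axis, log scale). Bars give 95% intervals for counting error that treat both counts as independent, with 1 library per time. Mature neutrophil genes stood at 1.50 at 72 h and 1.01 at 6 h, and non-myeloid tissue genes at 0.697 and 0.880.

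**Figure D3:**
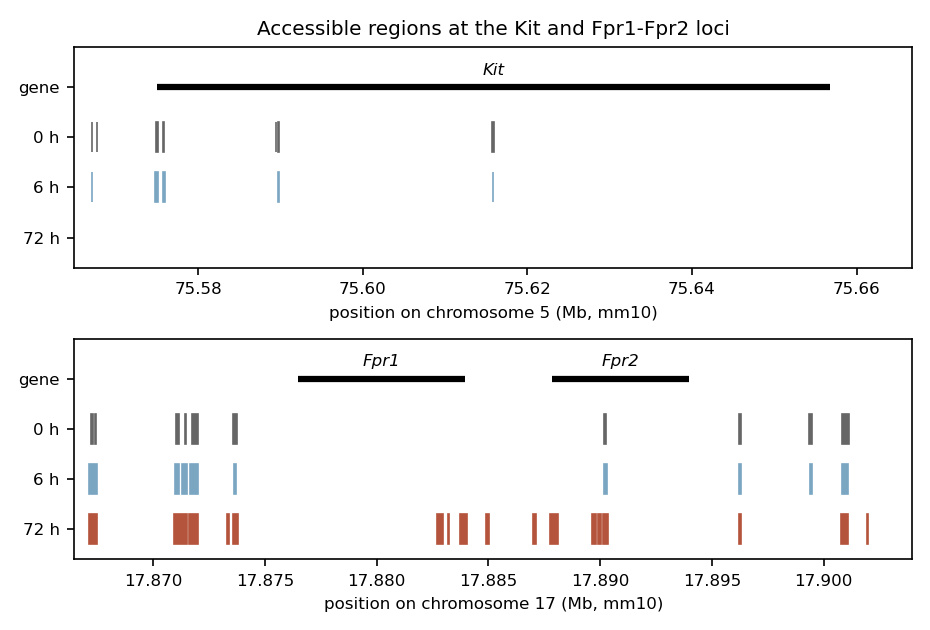
Regions listed at 0 h, 6 h and 72 h (rows, boxes to scale) along the Kit locus on chromosome 5 and the Fpr1 and Fpr2 loci on chromosome 17 (x axis, Mb of mm10), with gene spans as black bars. Kit had 0 regions at 72 h, while regions between and inside Fpr1 and Fpr2 were listed at 72 h that were absent at 0 h and 6 h.

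Genes with the most strong regions lost at 72 h were Scaf8, Ano6, Ttc29, Tacr1, Dnah8, Foxo6, St6galnac3, Rph3a, Adamts1 and Skap1, with 8 to 23 each. Dnah8, an axonemal dynein chain, went from 48 regions in its locus to 10, St6galnac3, a sialyltransferase, from 18 to 1, and Tacr1, the substance P receptor, from 24 to 3. The 23 regions assigned to Scaf8 lay outside the gene, from 3015159 to 3104775 near the start of chromosome 17, and the Scaf8 locus held 10 and 13 regions. Genes with the most strong regions gained were Ankrd11, Cd84, Ccl6, Creb5, Itpr1, Dock10, Plekhm1, Ninj2, Ccny and Ptprc, with 6 to 13 each. Cd84, a SLAM-family receptor of leukocytes, gained 8, led by a region of fold 51.5 at chromosome 1, 171823265 to 171823577, and its locus went from 7 to 16 regions. Ptprc, the pan-leukocyte antigen CD45, gained 6, and its locus went from 22 to 38. With the other assignment of regions and its other order of ties, 2 of the 10 lost and 6 of the 10 gained genes were shared.

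Strong regions lost at 72 h numbered 15494, or 15.7% (15.5 to 16.0) of the strong 0 h regions, and those gained numbered 5487, or 7.21% (7.03 to 7.40) of the strong 72 h regions. The excess of losses depended on the threshold: with a −log10 q of at least 10, 8663 were lost and 6606 gained, with a fold of at least 10 in either list, 4145 were lost and 4586 gained, and with a fold of at least 20, 373 and 843. Of all 0 h regions 59.8% (59.6 to 60.0) were overlapped at 72 h, and of 72 h regions 77.2% (76.9 to 77.4) were overlapped at 0 h. Strong regions at gene ends were overlapped at 72 h in 92.5% (92.1 to 92.9) of cases and strong distal ones in 82.3% (82.0 to 82.5).

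Losses at 72 h were uneven along the genome. The random gene lists were not matched on gene density, so list percentiles at 72 h may partly follow it. In the gene-poor part, 44.6% (43.9 to 45.4) of 0 h regions were overlapped at 72 h, against 58.2% (57.8 to 58.6) in the middle part and 62.9% (62.6 to 63.1) in the gene-dense part. For strong regions the shares were 72.9% (72.0 to 73.9), 82.4% (81.9 to 82.8) and 86.5% (86.2 to 86.8). At 6 h the parts lay closer together, at 70.2%, 76.3% and 77.7% for all regions and 96.4%, 97.3% and 97.8% for strong ones. By chromosome, 72 h regions numbered 71.8% of those at 0 h on chromosome 15 and 76.1% to 87.5% on the other autosomes and X, with X the highest.

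The third comparison, 72 h with 6 h, leaves out the 0 h library but shares the 72 h library with the second, so it is no independent check of it. Mature neutrophil genes stood apart here too, with 231 regions at 6 h and 302 at 72 h, 1.50 times (1.26 to 1.78) the change over all loci at percentile 100. Of the 28 loci 21 held more regions at 72 h and 4 fewer. Outside the range of random lists were also secondary and tertiary granule genes with a ratio of 1.27 (1.08 to 1.51) at percentile 99.9, p53 targets and apoptosis genes with 1.25 (1.07 to 1.48) at 99.9, myeloid transcription factors with 1.21 (1.01 to 1.44) at 98.7, inflammatory and NF-kB genes with 1.20 (1.03 to 1.41) at 99.8 and interferon response genes with 1.17 (0.959 to 1.43) at 99.3. Monocyte and macrophage markers, with 1.23 (0.966 to 1.56) at 99.1, were outside it only with Adgre1: without that gene they held 126 and 107 regions, a ratio of 0.971 (0.744 to 1.27) at percentile 50.6. The end ranks of the p53 list went the other way, with a median change of −4.02 points at percentile 1.58. Non-myeloid tissue genes had a ratio of 0.792 (0.613 to 1.02) at percentile 4.29, inside the range.

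Genes with the most strong regions lost from 6 h to 72 h were Scaf8, Dnah8, Skap1, Sik3, Pax2, Adamts1, St6galnac3, Fhad1, Ano6 and Mapt, with 7 to 20 each. Pax2, a developmental factor of the kidney, held 13 regions at 6 h and 4 at 72 h, and Mapt, which encodes tau, 27 and 14. Genes with the most gained were Rab8b, Cd84, Atp2b1, Sppl3, Plekhm1, Ankrd11, Ccl6, Gda, Itpr1 and Lcp2, with 5 to 8 each. Rab8b, a GTPase of membrane traffic, went from 25 regions to 44, and Lcp2, the adaptor SLP-76 of leukocyte signalling, from 18 to 28. With the other assignment and its other order of ties, 4 of the 10 lost and 6 of the 10 gained genes were shared. In all, 11162 strong regions were lost, 12.0% (11.8 to 12.2) of the strong 6 h regions, and 4169 were gained, 5.48% (5.32 to 5.65) of the strong 72 h regions. With a −log10 q of at least 10 the numbers were 8415 and 5128, with a fold of at least 10 they were 3880 and 3427, and with a fold of at least 20 the order turned, at 344 and 522.

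Most losses came after 6 h: 88.6% (88.1 to 89.1) of the strong regions lost at 72 h were still listed at 6 h. Of the strong regions gained at 72 h, 44.9% (43.6 to 46.2) were already listed at 6 h at some strength. Strong regions lost at both times numbered 1765, against 385 for independent lists and 931 if each loss depended on height in the 0 h list alone (861 to 1007 in 100 simulations). Both comparisons share the single 0 h library, so part of the excess may come from it. In the strongest 25%, 17 of the 20 lost at 6 h were also lost at 72 h.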

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

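The test of depth from the 0 h to 6 h retention curve and the calibration on other orders of the lists were chosen only after the first depth test was seen, and the tests at equal height and with 1 gene or 1 group of genes left out only after the shares by gene density and the counts per gene were seen. The lists below lay on opposite sides of 0 h at 6 h and at 72 h by regions in their loci; these differences were not tested, with 1 library at each time. Mature neutrophil genes held 235 regions at 0 h, 231 at 6 h and 302 at 72 h. Inflammatory and NF-kB genes held 334, 320 and 337. Nuclear envelope and lamina genes held 398, 395 and 403. Monocyte and macrophage markers held 147, 139 and 149. Mast cell, basophil and eosinophil markers held 79, 84 and 57. Erythroid and megakaryocyte markers held 172, 174 and 125.

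More regions in mature neutrophil loci at 72 h was weighed against splitting of wide regions and against a single gene or locus. Splitting was more frequent at 72 h, since 4.87% of the overlapped 0 h regions met several 72 h regions and 2.93% the other way round. Counted as merged regions, the list still stood at 1.62 (1.35 to 1.94) times the change over all loci, which argues against splitting as the cause, and leaving out any 1 of the 28 genes gave at least 1.47, the value without Fpr2. With genes of overlapping loci left out together, in 24 groups, the lowest value was 1.44 (1.21 to 1.73), without Fpr1 and Fpr2, which argues against a single gene or group. Several groups together were not left out; 20 of the 28 loci held more regions at 72 h than at 0 h and 5 fewer. Time in culture, a subset of cells that matured and the dTAG treatment itself remain open and untested, since no untreated 72 h library was analysed here.

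Strong 0 h regions missing at 72 h were weighed against lower depth and against a general loss of weak regions. Of 96046 strong 0 h regions listed at 6 h, 13729 were missing at 72 h, 7.71 times the 1780 that Poisson sampling at 0.859 of the 6 h depth predicts; the same calculation gave 0.608 to 3.06 in the 4 orders of the lists where regions were missing at 0 h or 6 h, so it is not exact, and 7.03 for strong 6 h regions listed at 0 h and missing at 72 h. From the observed 0 h to 6 h retention at each height, scaled to the 72 h depth, 4282 were predicted and 15494 missing, a ratio of 3.62. At equal height in the 0 h list, retention in the gene-dense part exceeded that in the gene-poor part by 10.3 percentage points (9.04 to 11.7) at 72 h. At 6 h the difference was 1.44 (0.803 to 2.10). Both intervals came from 1000 resamples of 1 Mb bins. A loss of all weak regions alike is thus not the whole cause. Regions were not matched on gene ends, where 92.5% of strong regions were overlapped at 72 h against 82.3% of distal ones. Gene density and gene ends were therefore not separated. A loss of accessibility that falls more on gene-poor chromatin may contribute, as a hypothesis; a library-specific bias against such chromatin stays open with 1 library.

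Fewer regions on chromosome 15 at 72 h was weighed against a lower copy number. Regions with a −log10 q below 10 numbered 55.1% of those at 0 h there and 59.5% to 76.1% on the other autosomes and X, with 86.3% and 90.4% to 97.2% already at 6 h. Among regions in all 3 lists, the median height rank of chromosome 15 changed by −1.19 points, within the −1.19 to 2.85 of the other autosomes and X, where heights lowered by 10% would have given −3.57. Medians move in steps because the folds are tied; the mean rank changed by −0.510 against −1.21 to 1.23 on those chromosomes. Chromosome Y, with 17 such regions, was left out. A copy-number fall of that size is therefore unlikely, a smaller one stays open, and no biological explanation was tested.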

How the results depend on the processing

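The minimum folds of 10 and 20, leaving out chromosome 15, merged regions and counting each region once were chosen after seeing the data; the other alternatives were set before the data were examined. Of 179 comparisons of a main value with an alternative, 119 kept it within its interval or within 1.5 times and 60 moved. The cause of each move was not tested unless the alternative's construction gives it. The tally is no measure of robustness. It includes 90 gene-list ratios, judged against their counting intervals, of which only 1 moved. It also includes alternatives that could not differ, such as unmerged lines and the 72 h list among equal-sized lists. With a −log10 q of at least 10 the lists held 82233, 85429 and 81072 regions at 0 h, 6 h and 72 h, by construction. The share of 0 h regions overlapped at 6 h was 88.8% with that q, 82.0% with equal-sized lists, 66.9% when 50% of both regions had to overlap and 73.1% by summit; at 72 h the shares were 72.5%, 69.8%, 47.3% and 57.1%. For 6 h regions at 0 h they were 85.5%, 82.0%, 68.5% and 74.4%, and for 72 h regions at 0 h 76.3%, 72.3%, 59.4% and 73.8%. The upper 25% included ties at the cutoff, with 46637 regions at 0 h. In it, strong regions lost and gained numbered 20 and 21 at 6 h and 980 and 530 at 72 h. From 6 h to 72 h they numbered 611 and 309, and 17 were lost at both times. With a −log10 q of at least 10, 688 were lost and 893 gained at 6 h and 8663 were lost at 72 h. With a fold of at least 10, 148 were lost and 173 gained at 6 h, 4145 were lost at 72 h and 3880 from 6 h to 72 h; with a fold of at least 20, lost and gained numbered 15 and 18 at 6 h, 373 and 843 at 72 h, and 344 and 522 from 6 h to 72 h. Gene-end shares at 0 h, 6 h and 72 h were 10.7%, 10.8% and 13.1% within 500 bp and 35.5%, 35.2% and 39.5% within 5 kb, and 17.3% and 17.1% at 0 h and 6 h in equal-sized lists. With equal-sized lists the gene-poor, middle and gene-dense shares were 76.6%, 81.1% and 83.2% at 6 h and 55.4%, 67.8% and 72.7% at 72 h, in the same order as before. The 18 gene-list ratios of 72 h to 0 h, the only list ratios recomputed, stayed within their intervals in equal-sized lists, with 50 kb flanks, with merged regions and with each region counted once; with a fold of at least 10, 17 did, and secondary and tertiary granule genes stood at 0.12 on the log2 scale. The log2 ratio changed sign in 8 of 90 such comparisons, in 4 lists (progenitor and stem, primary granule, lymphoid and housekeeping genes), none of them outside the range of random lists in the main setting. With 50 kb flanks, percentiles moved inside that range for interferon response genes (96.5) and the cohesin list (93.2). They also did so for the cohesin list (76.9) with merged regions and non-myeloid tissue genes (3.15) in equal-sized lists. With a fold of at least 10, percentiles of the granule (80.6), p53 (95.3) and non-myeloid (3.56) lists moved inside it. They moved outside it for monocyte markers in equal-sized lists (99.3), with merged regions (98.9), with a fold of at least 10 (99.7) and with each region counted once (99.4), and for mast cell, basophil and eosinophil markers with a fold of at least 10 (1.58). With regions assigned inside gene spans, 3 lost and 2 gained of 10 named genes were shared at 6 h. At 72 h 2 and 6 were shared, and from 6 h to 72 h 4 and 6. That alternative also ordered tied genes by symbol, so these numbers do not measure the assignment alone. Of 36 comparisons for gene-end counts per list, 33 stayed within 1.5 times. Leaving lines unmerged, using all sequences or taking strong by fold changed 0 regions. Motif alternatives were not run. No paired analysis was possible because each time point has 1 library. Depth limits the weakest regions, whose summits hold as few as 3 fragments.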

Other observations

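All values in this part were picked after they were seen. The Adgre1 locus on chromosome 17 held 13 regions at 0 h, 13 at 6 h and 42 at 72 h, while C1qa, C1qb and C1qc, the complement genes of macrophages, held 9, 4 and 2, then 7, 4 and 2, then 6, 2 and 1 regions, and Fcgr1 12, 7 and 8; regions in overlapping loci count for each gene. The end ranks of Bcl2a1a, Bcl2a1b and Bcl2a1d, survival genes of myeloid cells, were 49, 37 and 11 at 0 h and 75, 77 and 58 at 72 h. Reads shared between such copies were not examined here.

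Neutrophil loci differed among themselves. Il1r2, Cd14 and Clec4e had end ranks of 25, 24 and 24 at 0 h and 95, 62 and 61 at 72 h. Csf3r, the receptor for G-CSF, held 11, 9 and 8 regions, Selplg 24, 21 and 20, and Fcnb, a ficolin of immature neutrophils, 5, 3 and 1. Cxcr4, which holds neutrophils in the marrow, had end ranks of 52, 47 and 27, and 5 strong regions near it were lost at 72 h.

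A few very high and narrow regions were in a single list. With a fold of at least 100, 4 of 3826 regions at 0 h, 5 of 5392 at 6 h and 3 of 7056 at 72 h overlapped nothing in the other lists, with median lengths of 80, 85 and 116 bp against 772, 722 and 542 bp for all regions of that height. Strong regions lost or gained with the highest folds, 955 at 0 h and 1006 at 6 h, came from this set and are poor candidates for follow-up.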
